A study of Mus musculus with 10 samples.

How the data were processed

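Each sample is a pool of neutrophils from the blood of 10 mice, and 1 array was run per sample from 75 ng of total RNA, amplified and labelled with biotin per the labels' protocols. The deposited values are log2 signals per probe set; RMA and limma are named in the submitters' processing notes, with no versions, and what each did is not given in the sources used here. RMA usually corrects the background, normalizes quantiles between arrays and sums the probes of a set; the deposited log2 columns did not share 1 distribution (interquartile range 2.04 to 2.99), so whether quantiles were normalized over these 10 arrays alone is unknown. No genome coordinates were used.

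Probe sets were named through the platform's gene table. Of 45101 probe sets, 34958 carried 1 gene symbol, 932 several, and 9211 were not in that table, 51 of them control probe sets. Symbols were updated by Entrez number through a RefSeq gene table of assembly GRCm38.p6 for 34754 probe sets, and no coordinates were taken from it. Probe sets with several symbols or none were left out of the gene tests. Each of 18194 genes was represented by its probe set with the highest mean over the 10 arrays, with no filter on dim probe sets. Of 78 named genes, 35 had more than 1 probe set, and for Inpp4a, Tcn2, Tgfb1 and Tnfsf13b another probe set had the opposite sign over 5 pairs. Other probe sets of further named genes kept the sign but differed in size, smaller in many cases, and only some of these values are printed below.

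LDN and HDN were compared with limma's lmFit and eBayes (limma 3.58.1, R 4.3.3) with the pair as a fixed block, two-sided, and p-values were adjusted after Benjamini and Hochberg over all genes, with a threshold of 0.05. Fold changes are LDN minus HDN on the log2 scale, and standard errors come from the same model. The pools are the replicates. With the pair as a block, standard errors describe the spread of the LDN minus HDN differences between pairs, moderated over genes by eBayes. The spread between pools of a group is given by the SD where one is printed. The study's design text states that LDN and HDN were purified from pooled blood and compared as matched pairs, and an LDN and an HDN pool were taken as a pair here because they carry the same number. As a check, deviations from the group means were correlated within each pair. The r was 0.08, 0.20, 0.08, 0.06 and 0.17 in pairs 1 to 5, and 2 of the 5 HDN arrays correlated best with their own LDN partner. No 2 arrays held identical values.

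Gene lists (22 of neutrophil programs and 9 of markers of other blood cells, 725 entries, of which 638 were measured) were fixed before the data were examined, as were the tests, the named-gene rule and most of the other settings given below. The lists on G protein-coupled receptors, PI3K and TGF-beta were included because the study is known to concern them. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 between genes, beside camera with an estimated correlation and fry, with Benjamini-Hochberg adjustment over 31 lists. Named genes are the 10 with the largest rise and the 10 with the largest fall among genes past the threshold that changed the same way in all 5 pairs, leaving out predicted genes and clones; up to 3 such members of each list, or the member with the smallest p where none passed; and a fixed set of identity and study genes. Of the fixed set, Ly6g has no probe set with a single symbol here and was not analysed here, and some other genes are not reported. The unadjusted thresholds, the fold threshold of 2 and all list counts use the same fit.

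The comparison over pairs 1 to 3, and one without HDN arrays 4 and 5 that keeps their LDN partners, were added after the data were seen. Fixed in advance were the fit without the pair block or with the pair as a random block, each pair left out in turn, filters at the 30th percentile and at the median of probe set means, the mean or the most variable probe set of a gene, 3 scalings between arrays, eBayes with trend and robust variances, and array weights.

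The scripts were tested on simulated data for the same 18194 genes, with 200 genes changed. With the spread of the 5 pairs, the test called 0%, 1.49% and 40.9% of genes changed by 0.5, 1 and 2 on the log2 scale, with 0 false calls. With the spread of pairs 1 to 3 it called 0%, 29.9% and 77.3%, with 0 false calls. In each case the shifted list passed camera, as did 0 and 1 unshifted lists. Noise was drawn independently for each gene and alike on every array, so no array stood apart. The simulated error rates do not carry over to these data, where swaps of LDN and HDN within pairs passed up to 23 lists. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).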

Results

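Gene expression was measured in neutrophils from the blood of diabetic mice infected with Staphylococcus aureus. The animals were 8-week-old male db/db mice, which carry a mutation of the leptin receptor gene Lepr and become obese and diabetic. They received 5e7 CFU of strain SF8300 intravenously, and blood was taken 48 h later. Blood of 10 mice was pooled, and density centrifugation followed by a neutrophil purification kit gave a low-density (LDN) and a high-density (HDN) neutrophil preparation. Each preparation was hybridised to 1 Affymetrix array, giving 5 LDN and 5 HDN arrays in 5 matched pairs. The comparison asks which transcripts differ between LDN and HDN of the same infected mice. The median signal of an array lay between 4.63 and 5.01 (log2) over all probe sets, and the number of arrays limits the precision of every value.

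HDN 4 and HDN 5 stood apart from the other 8 arrays. Pearson's r over all probe sets with those 8 was 0.836 to 0.869 for HDN 4 and 0.630 to 0.688 for HDN 5, against at least 0.943 among the 8. The actin probe set nearest the 3' end read 12.03 on HDN 4 and 9.06 on HDN 5, against 13.6 to 14.2 elsewhere, while the hybridisation controls read 12.2 and 12.5 against 10.7 to 11.4. Transcripts of haem synthesis were high on both: Alas2, the first enzyme of that pathway in red cell precursors, read 13.7 and 13.3, against 9.51 to 12.9 on the other 8. For this reason counts and gene lists are given over all 5 pairs, the design fixed in advance, and over pairs 1 to 3, a comparison chosen after the data were seen. Values of single genes are over 5 pairs unless pairs 1 to 3 are named. LDN 4 and LDN 5 differed from LDN 1 to 3 as well. Their hybridisation controls read 11.05 and 11.04 against 10.73 to 10.78. The mean signal of the NK cell marker list was 8.01 and 8.44 on them against 6.52 to 7.42. The comparison over pairs 1 to 3 thus leaves out pools that differed in both groups, and the cause was not tested.

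**Figure D1:**
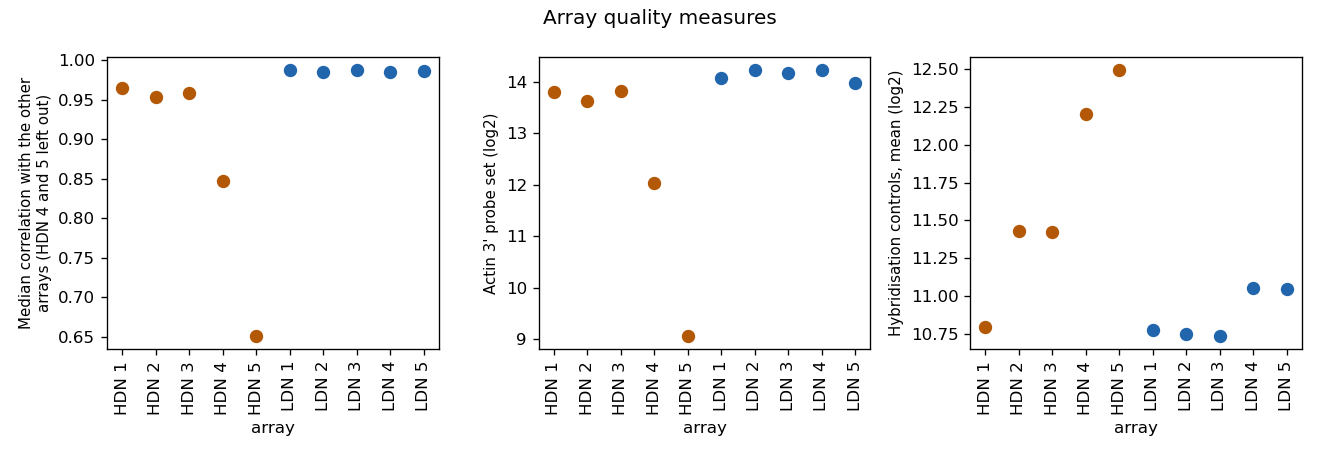
Each point is 1 array, HDN in brown and LDN in blue; the vertical axes show the median Pearson's r over probe sets with the arrays other than HDN 4 and HDN 5, the log2 signal of the 3' actin probe set, and the mean log2 signal of the hybridisation controls. HDN 4 and HDN 5 had a median r of 0.847 and 0.651 and an actin signal of 12.03 and 9.06, the lowest 2 of the 10 arrays in both measures.

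LDN carried more transcript than HDN of genes such as Ltf, Camp, Itgam and Ifit1, and less of genes such as Snhg1, Tfrc and Blk. The largest rise was that of Ltf, the secondary granule protein lactoferrin, from 7.36 ± 1.88 (SD, n = 5) in HDN to 11.3 ± 0.58 in LDN, a log2 fold change of 3.94 ± 0.60 (SE), or 15.4-fold (limma, Benjamini-Hochberg adjusted p = 0.0304), and 6.80-fold over pairs 1 to 3. Next, with the value over pairs 1 to 3 second, came Lipg (endothelial lipase, 3.73 and 2.70), Cd300lb (a myeloid activating receptor, 3.56 and 2.60), Mtus1 (3.45 and 2.27), Mgam (the glucosidase maltase-glucoamylase, 3.40 and 2.84) and Lin28a (3.24 and 2.59). Crispld2 (3.22 and 2.21), Tcn2 (the vitamin B12 carrier transcobalamin, 3.22 and 2.03), Ppp1r3b (a glycogen-targeting phosphatase subunit, 3.17 and 2.31) and Olfm4 (a granule protein, 3.14 and 2.44) followed. The other 4 probe sets of Tcn2 gave smaller values over 5 pairs, -0.05, 1.77, 1.94 and 2.01. The largest falls were those of Snhg1, a host gene of small nucleolar RNAs (log2 fold change -2.91 and -2.47), Mcpt2 (-2.498 and -3.02), Bola3, a factor of mitochondrial iron-sulphur cluster assembly (-2.32 and -1.86), the small nucleolar RNA gene Snord104 (-2.13 and -1.94) and the transferrin receptor gene Tfrc (-2.13 and -2.11). Farsb (a subunit of phenylalanyl-tRNA synthetase, -1.87 and -2.46), Chd3 (a chromatin remodeller, -1.83 and -1.96), Plaat3 (-1.83 and -1.24), Hgh1 (-1.77 and -1.59) and the immunoglobulin kappa locus Igk (-1.74 and -2.10) completed the list. Dimmer probe sets of Tfrc gave only -0.55 to -0.16 over 5 pairs, those of Bola3 -0.66 and -0.28, and a dimmer one of Lin28a 0.41. Mcpt2 read 3.14 to 3.70 on the LDN arrays, where the lower quartile of all probe sets was 3.47 to 3.53. Its fall is therefore a rough value. Of the 45 named genes that rose, 42 had a smaller shift over pairs 1 to 3 (median 1.95 in place of 2.57), as did 6 of the 14 that fell (median -1.95 in place of -1.83). All passed the test in both comparisons, which share pairs 1 to 3 and so are not independent.

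Of 18194 genes, 525 were higher and 75 lower in LDN over 5 pairs, and 565 of them differed at least 2-fold (limma, Benjamini-Hochberg adjusted p under 0.05). Every one of the 600 moved in the same direction in all 5 pairs. Without pair 1, 2, 3 or 4, no gene passed that limma test, while 2901 to 4006 had an unadjusted p under 0.05. Without pair 5, 745 were higher and 231 lower. Over pairs 1 to 3, 2756 were higher and 2912 lower, 2409 of them at least 2-fold. All 525 and all 75 genes called over 5 pairs were among these, each in its direction. Pairs 1 to 3 are part of the 5 pairs, and 5668 of 18194 genes passed in them. The overlap is therefore not a replication. With no replicate block, so that pairs were ignored, 867 genes were higher and 339 lower. Cyclic loess scaling gave 873 higher and 745 lower genes, 54.0% higher in place of 87.5%, and quantile scaling 70.6%. The median log2 fold change of all genes was -0.13 over 5 pairs, -0.02 after each array was centred on its median, and 0.03 over pairs 1 to 3.

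**Figure D2:**
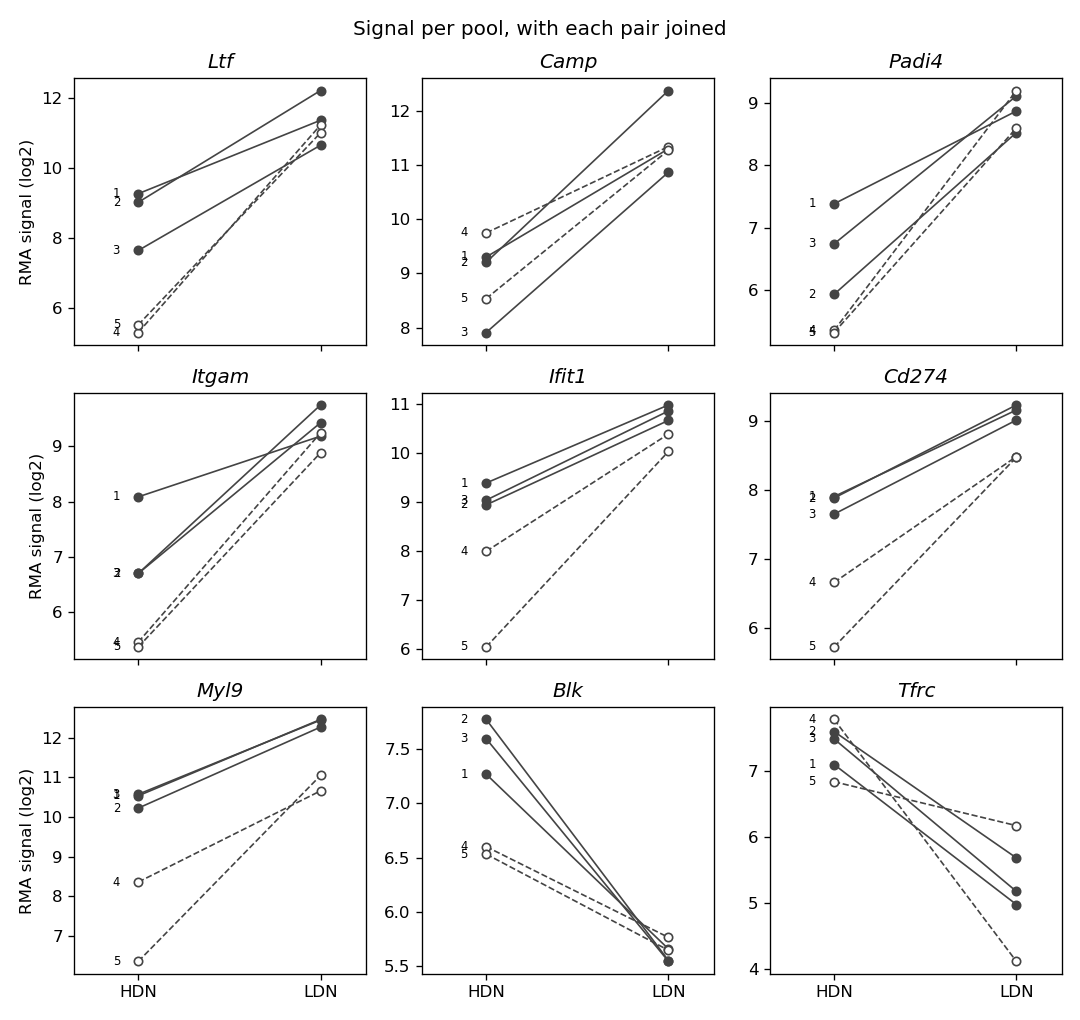
RMA signal (log2, vertical axis) of 9 genes in each HDN and LDN pool, with lines joining the pools of 1 pair and the pair number at the HDN point; open points and dashed lines mark pairs 4 and 5. Ltf, Camp, Padi4, Itgam, Ifit1, Cd274 and Myl9 were higher in LDN in all 5 pairs, and Blk and Tfrc were lower in all 5.

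Secondary granule genes, whose products neutrophils make before they leave the marrow, were higher in LDN. Camp, the cathelicidin precursor, rose by 2.49 ± 0.28 (SE) on the log2 scale over 5 pairs and by 2.70 ± 0.22 over pairs 1 to 3. Ltf and Olfm4 rose by 2.77 and 2.44 over pairs 1 to 3. Of 15 measured secondary granule genes, 3 rose and none fell over 5 pairs (9 rose when adjusted over the list alone), and 13 rose over pairs 1 to 3 (14 adjusted over the list alone). The list passed the camera test over 5 pairs (adjusted p = 3.2e-08, but adjusted p = 0.381 with an estimated correlation) and over pairs 1 to 3 (adjusted p = 7.4e-08, and 0.484 with an estimated correlation). The list of tertiary granule and secretory vesicle genes was led by Padi4 (2.71 ± 0.35) and Adam8 (2.57 ± 0.43). Padi4 encodes the enzyme that citrullinates histones in extracellular traps. It had been put on this list although it is not a granule protein, so Adam8 is the only granule gene of the 2. Of the 10 measured genes of the list, Padi4 and Adam8 alone rose over 5 pairs and 5 rose over pairs 1 to 3 (camera adjusted p = 0.0103 and 0.0257, and adjusted p = 0.381 and 0.484 with an estimated correlation). Under cyclic loess the median of the tertiary list over 5 pairs was -0.165 in place of 1.56. The tertiary call over pairs 1 to 3 was lost after cyclic loess (adjusted p = 0.0809, median 0.14 in place of 0.43) and quantile scaling (adjusted p = 0.0621, median 0.20). The secondary granule median was 0.79 to 1.71 in pairs 1 to 3, 1.99 in pair 4 and 5.06 in pair 5. Mmp9, the gelatinase of these granules, differed by 3.05 ± 0.89 without passing the test over 5 pairs (limma, Benjamini-Hochberg adjusted p = 0.114), and rose by 1.42 ± 0.17 over pairs 1 to 3.

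Primary granule genes are the earliest made, and none of the 10 measured passed the test over 5 pairs (4 higher adjusted over the list alone), and 4 rose and 2 fell over pairs 1 to 3. Prtn3, proteinase 3, had the smallest p over 5 pairs, with a difference of 1.26 ± 0.31 (limma, Benjamini-Hochberg adjusted p = 0.0808), and rose by 1.00 ± 0.30 over pairs 1 to 3. Mpo, myeloperoxidase, differed by 0.70 ± 0.22 over 5 pairs and rose by 0.73 ± 0.17 over pairs 1 to 3. Elane, neutrophil elastase, differed by 0.06 ± 0.18 and 0.24 ± 0.14, past the test in neither. The median of the list was positive in each pair (0.14 to 1.397). Its mean over pairs 1 to 3 was 0.02, and the mean signal was lower in LDN in pair 1 (8.38 in HDN, 8.04 in LDN) and pair 3 (8.14 and 8.06). The list passed camera over 5 pairs (adjusted p = 0.0351, 0.381 with an estimated correlation, 0.294 after cyclic loess and 0.120 after quantile scaling) but not over pairs 1 to 3 (adjusted p = 0.514). Of 13 neutrophil precursor genes, Tfrc fell and none rose over 5 pairs, and 4 rose and 6 fell over pairs 1 to 3 (camera adjusted p = 0.939 and 0.226). In pairs 1 to 3 the medians of the B, T and NK cell marker lists were -2.88, -2.84 and -2.03, so lymphocyte transcripts were lower in the same LDN pools in which granule genes were higher.

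Genes of the mature neutrophil surface were higher in LDN as well. Itgam, the CD11b integrin chain, rose by 2.83 ± 0.40 (SE) over 5 pairs and by 2.29 ± 0.33 over pairs 1 to 3. Ccr1, a chemokine receptor, rose by 1.96 ± 0.34, and Trem1, an amplifier of inflammatory signalling, by 1.57 ± 0.29. These 3 of the 18 measured genes passed over 5 pairs (17 adjusted over the list alone), and 17 rose over pairs 1 to 3 (camera adjusted p = 4.0e-11 and 3.1e-10, and adjusted p = 0.381 and 0.484 with an estimated correlation). Their median was 0.97 to 1.59 in pairs 1 to 3, where B cell markers were lower and platelet markers higher in LDN (medians -2.88 and 1.34), and 2.59 and 4.75 in pairs 4 and 5, whose HDN arrays stood apart. The chemokine receptor Cxcr2 differed by 2.95 ± 0.66 and the G-CSF receptor Csf3r by 2.52 ± 0.58, short of the threshold over 5 pairs (limma, Benjamini-Hochberg adjusted p = 0.0641 and 0.0689), and rose by 1.70 and 1.59 over pairs 1 to 3. Among 10 aged or activated neutrophil genes, Siglecf (2.92), Tlr4 (2.65) and Cd274 (the checkpoint ligand PD-L1, 1.71 ± 0.27) rose over 5 pairs, while over pairs 1 to 3 a total of 4 rose and 4 fell (camera adjusted p = 0.00163 and 0.468, the first with adjusted p = 0.447 with an estimated correlation and a median of -0.22 under cyclic loess). Cxcr4, the receptor that retains neutrophils in the marrow, differed by 0.76 ± 0.73 over 5 pairs (limma, Benjamini-Hochberg adjusted p = 0.528) and fell by 0.59 ± 0.17 over pairs 1 to 3 (limma, adjusted p = 0.0330). Its difference was -0.44 after cyclic loess scaling and -0.64 with array weights.

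Some interferon-induced genes rose in LDN. Ifit1 and Ifit3, which bind viral RNA or partner in doing so, rose by 2.31 ± 0.38 and 2.23 ± 0.26 over 5 pairs, and the kinase gene Cmpk2 by 2.38 ± 0.45. Of 30 measured genes, 8 rose and none fell over 5 pairs (23 adjusted over the list alone), and 24 rose over pairs 1 to 3 (camera adjusted p = 1.9e-12 and 9.2e-11, and adjusted p = 0.381 and 0.484 with an estimated correlation). The interferon median was 0.96 to 1.18 in pairs 1 to 3, 2.02 in pair 4 and 3.24 in pair 5. In the same pairs 1 to 3 lymphocyte markers were lower and platelet markers higher (medians -2.88 for B cells and 1.34 for platelets). Some pattern recognition genes rose, with Tlr4, Tirap (an adaptor of Toll-like receptors, 2.498 ± 0.27) and Irak3 (a brake on that pathway, 2.39 ± 0.46) in front. Of these 27, 6 rose over 5 pairs and 17 rose and 2 fell over pairs 1 to 3 (camera adjusted p = 1.7e-07 and 7.6e-06, and adjusted p = 0.381 and 0.484 with an estimated correlation). Cytokine genes that rose over 5 pairs numbered 5 of 31, among them the TNF family members Tnfsf14 (2.98 ± 0.43) and Tnfsf13b (BAFF, 2.04 ± 0.18) and the interleukin-1 receptor antagonist Il1rn (2.62 ± 0.49), with 13 higher and 3 lower over pairs 1 to 3. Dimmer probe sets of Tnfsf13b gave 0.004 and -0.10 over 5 pairs. The cytokine list passed camera (adjusted p = 0.0140 and 0.00612, and adjusted p = 0.381 and 0.484 with an estimated correlation), and its median over 5 pairs was -0.08 under cyclic loess in place of 0.20. Gadd45b alone of 22 NF-kB response genes rose over 5 pairs (1.47 ± 0.21), against 12 higher and 3 lower over pairs 1 to 3 (camera adjusted p = 6.8e-05 and 0.0426, and adjusted p = 0.447 and 0.494 with an estimated correlation). The NF-kB call over pairs 1 to 3 was lost after median centring, cyclic loess and quantile scaling (adjusted p = 0.0505, 0.102 and 0.0834).

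The list of leukocyte G protein-coupled receptors was led by Adgrg3, an adhesion receptor of granulocytes, which rose by 2.98 ± 0.36 (SE) over 5 pairs. The nucleotide receptor genes P2ry13 and P2ry12 rose by 2.73 ± 0.39 and 2.67 ± 0.38. P2ry12 is also a receptor of platelets, whose markers were higher in the same LDN pools. Of 57 measured receptors, 9 rose and none fell over 5 pairs (camera adjusted p = 0.000485, and 0.381 with an estimated correlation). Over pairs 1 to 3, 22 rose and 17 fell, the median was 0.28 and the mean -0.04, and the list did not pass (camera adjusted p = 0.222). B and T cell markers were lower in the same LDN pools (medians -2.88 and -2.84), and which cells carried the receptors that fell was not tested.

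Of 31 genes of PI3K and AKT signalling, 3 rose over 5 pairs: Pik3cb, a catalytic subunit of the kinase (2.09 ± 0.38), Inpp4a, a phosphoinositide phosphatase (1.43 ± 0.19), and Pik3r5, the regulatory subunit of the form activated by G protein-coupled receptors (1.34 ± 0.25). A dimmer probe set of Inpp4a read -0.11. In pairs 1 to 3, 10 rose and 5 fell. The list passed camera over 5 pairs only (adjusted p = 0.000135 and 0.242, the first with adjusted p = 0.432 with an estimated correlation). After cyclic loess that call was lost (adjusted p = 0.0559) and the median was 0.18 in place of 0.82. By pair, the median was 0.06 to 0.19 in pairs 1 to 3, 1.75 in pair 4 and 1.65 in pair 5. Of 28 genes of TGF-beta activation and signalling, Ltbp1, which tethers latent TGF-beta to the matrix, rose by 1.68 ± 0.23, and Thbs1, which can release it, by 1.44 ± 0.18. With no replicate block for the pairs neither gene passed the test. Dimmer probe sets of Ltbp1 gave 0.01 and 0.65 over 5 pairs, and a dimmer one of Thbs1 gave 1.19. Both genes were higher on LDN 1 to 3 (Thbs1 9.87 to 11.17, Ltbp1 6.76 to 7.31) than on LDN 4 and 5 (Thbs1 8.95 and 8.497, Ltbp1 5.47 and 5.69), as was the mean of the platelet marker list (11.03 to 11.22 against 9.50 and 9.82). The co-receptor gene Tgfbr3 fell by 1.54 ± 0.21, while a dimmer probe set of it gave -0.45 over 5 pairs and -0.06 over pairs 1 to 3. Over pairs 1 to 3, 6 rose and 7 fell, and the list did not pass camera in either comparison (adjusted p = 0.118 and 0.888, with a median of 0.06 and a mean of -0.01 over pairs 1 to 3). Tgfb1 differed by 0.89 ± 0.38 over 5 pairs (limma, Benjamini-Hochberg adjusted p = 0.229) and by 0.21 ± 0.14 over pairs 1 to 3 (adjusted p = 0.342). Itgb8, a subunit of a TGF-beta-activating integrin, read 2.17 in HDN and 2.19 in LDN, near the low end of the scale.

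Some glycolysis genes were higher in LDN, led by the 2 regulators of fructose 2,6-bisphosphate Pfkfb4 (2.70 ± 0.38) and Pfkfb3 (2.00 ± 0.25) and by the lactate exporter Slc16a3 (1.95 ± 0.28). These 3 of 18 rose over 5 pairs (12 adjusted over the list alone) and 11 rose over pairs 1 to 3 (camera adjusted p = 3.2e-08 and 2.8e-05, and adjusted p = 0.381 and 0.484 with an estimated correlation). A dimmer probe set of Pfkfb3 gave 0.03 over 5 pairs. The median of the glycolysis list was 0.53 to 1.01 in pairs 1 to 3, where the B and T cell medians were -2.88 and -2.84 and the platelet median 1.34. It was 2.82 and 4.02 in pairs 4 and 5, whose HDN arrays stood apart. No oxidative phosphorylation gene of 32 passed over 5 pairs (camera adjusted p = 0.0513). Over pairs 1 to 3, 12 fell and 1 rose (camera adjusted p = 0.00267, and 0.605 with an estimated correlation). The median of that list was 0.25 over 5 pairs, -1.02 after cyclic loess, -0.33 after quantile scaling and -0.35 over pairs 1 to 3; Sdhd, its member with the smallest p, differed by 0.90 ± 0.24. Of 14 genes of the NADPH oxidase and extracellular traps, Padi4, also on the tertiary granule list, alone rose over 5 pairs, and 9 rose and 2 fell over pairs 1 to 3 (camera adjusted p = 0.000151 and 0.00532, and adjusted p = 0.432 and 0.484 with an estimated correlation). After cyclic loess neither call was kept (adjusted p = 0.0872 and 0.0527), and the median over 5 pairs was 0.50 in place of 1.77.

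Genes linked to suppressive neutrophils rose in part. Cd274 and the fatty acid transporter gene Slc27a2 (1.37 ± 0.20) were 2 of 18 that rose over 5 pairs, and 11 rose over pairs 1 to 3 (camera adjusted p = 5.1e-06 and 3.0e-06, and adjusted p = 0.381 and 0.484 with an estimated correlation). The list median was 0.64 to 1.06 in pairs 1 to 3, where B cell markers were lower and platelet markers higher in LDN (medians -2.88 and 1.34). It was 0.94 and 1.61 in pairs 4 and 5, whose HDN arrays stood apart. Arg1, arginase, differed by -0.32 ± 0.41 over 5 pairs and by 0.14 ± 0.38 over pairs 1 to 3 (limma, Benjamini-Hochberg adjusted p = 0.622 and 0.846). S100a8, an abundant neutrophil cytosolic protein gene, read 14.3 in HDN and 14.6 in LDN, a difference of 0.28 ± 0.17 (-2.00 after cyclic loess, past the test in neither). These readings lie near the highest signal of each array (14.66 to 14.89), where a probe set can saturate, so the size of that difference says little. Hmox1, haem oxygenase, rose by 1.198 ± 0.23 and was the 1 gene of 28 immediate early and heat shock genes past the test over 5 pairs, while 10 rose and 7 fell over pairs 1 to 3 (camera adjusted p = 0.00133 and 0.888, the first with adjusted p = 0.502 with an estimated correlation). Itgam was the 1 gene of 13 Fc and complement receptors that rose over 5 pairs, against 7 higher and 3 lower over pairs 1 to 3 (camera adjusted p = 0.00221 and 0.0707, the first with adjusted p = 0.381 with an estimated correlation). No apoptosis or survival gene of 17 passed over 5 pairs, with Fas at 1.26 ± 0.27, and 8 rose and 4 fell over pairs 1 to 3 (camera adjusted p = 0.00148 and 0.0983, the first with adjusted p = 0.381 with an estimated correlation and a median of -0.02 under cyclic loess).

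Transcripts of lymphocytes were lower in LDN in pairs 1 to 3, and over 5 pairs in part. The B cell genes Blk, a Src-family kinase of B cells, Cr2, a complement receptor, and Ebf1, a transcription factor of the lineage, fell by 1.53 ± 0.27, 1.41 ± 0.20 and 1.28 ± 0.23 (SE) over 5 pairs. These were 3 of 17 B cell markers over 5 pairs, and 16 fell over pairs 1 to 3 (camera adjusted p = 1.6e-06 and 1.4e-15, and adjusted p = 0.386 and 0.484 with an estimated correlation). No T cell marker of 19 passed over 5 pairs, with Trat1 nearest at -1.05 ± 0.22 (limma, Benjamini-Hochberg adjusted p = 0.0584), and 18 fell over pairs 1 to 3 (camera adjusted p = 1.5e-05 and 7.3e-17, and adjusted p = 0.406 and 0.349 with an estimated correlation). No NK cell marker of 13 passed over 5 pairs (Xcl1, -1.19 ± 0.43), and 12 fell over pairs 1 to 3 (camera adjusted p = 0.0856 and 9.4e-09, the second with adjusted p = 0.484 with an estimated correlation). The mean signal of the B cell list was 8.55, 8.89 and 8.92 on HDN 1 to 3, 6.07 and 6.02 on HDN 4 and 5, and 6.04 to 6.18 on the 5 LDN arrays. In pairs 4 and 5 the list medians were -0.15 and -0.02 for B cells, -0.18 and 0.35 for T cells, and 0.09 and 1.61 for NK cells, so T and NK markers did not run lower in LDN in both of those pairs. Of 14 dendritic cell markers, many of them antigen presentation genes that B cells also express, none passed over 5 pairs (Ciita, -1.73 ± 0.35) and 8 fell over pairs 1 to 3 (camera adjusted p = 0.000605 and 5.4e-06, and adjusted p = 0.381 and 0.484 with an estimated correlation).

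Cell cycle and ribosomal protein genes were lower in LDN in pairs 1 to 3, the pairs in which lymphocyte genes were lower. Of 35 cell cycle genes, 33 fell over pairs 1 to 3 and none passed over 5 pairs, where Tk1, thymidine kinase, came nearest at -1.05 ± 0.22 (camera adjusted p = 1.4e-15 over pairs 1 to 3 and 0.0184 over 5 pairs, and adjusted p = 0.484 and 0.705 with an estimated correlation). The cell cycle median was 0.75 in pair 4 and 1.44 in pair 5, the opposite direction. Of 21 cytosolic ribosomal protein genes, 19 fell over pairs 1 to 3 and none passed over 5 pairs, where Rps19 came nearest at -1.12 ± 0.24 (camera adjusted p = 4.4e-11 and 0.000144, and adjusted p = 0.484 and 0.451 with an estimated correlation), with a median of -0.23 in pair 4 and 0.02 in pair 5.

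Platelet and megakaryocyte genes were higher in LDN. Myl9, a myosin light chain, rose by 2.57 ± 0.45 (SE), Alox12, the platelet lipoxygenase, by 1.91 ± 0.33, and Treml1, a receptor of platelet granules, by 1.74 ± 0.31 over 5 pairs. With no replicate block for the pairs, none of these 3 passed the test. Of 18 markers, 7 rose over 5 pairs and all 18 over pairs 1 to 3 (camera adjusted p = 1.4e-12 and 4.5e-13, and adjusted p = 0.381 and 0.400 with an estimated correlation). The list mean was 11.03 to 11.22 on LDN 1 to 3, 9.50 on LDN 4 and 9.82 on LDN 5, against 9.62 to 9.89 on HDN 1 to 3, 8.04 on HDN 4 and 6.57 on HDN 5. The list median was positive in each pair, 1.403 in pair 4 and 3.13 in pair 5. Hdc, histidine decarboxylase, rose by 2.87 ± 0.53 and was the 1 gene past the test among 10 basophil and mast cell markers, of which 6 rose and 3 fell over pairs 1 to 3 (camera adjusted p = 0.0309 and 0.0661, the first with adjusted p = 0.381 with an estimated correlation).

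Among 20 erythroid markers only Tfrc fell over 5 pairs, and 7 fell and 2 rose over pairs 1 to 3 (camera adjusted p = 0.00127 and 0.00857, and adjusted p = 0.454 and 0.484 with an estimated correlation). Of 22 monocyte and macrophage markers none passed over 5 pairs (F13a1, the coagulation factor XIII A chain, 1.97 ± 0.56), and 2 rose and 5 fell over pairs 1 to 3 (camera adjusted p = 0.328 and 0.0802). The monocyte median over 5 pairs was 0.21, and -0.57 after cyclic loess, where the list passed as lower in LDN (adjusted p = 0.0290). It also passed as lower over pairs 1 to 3 after cyclic loess (adjusted p = 0.0119) and quantile scaling (adjusted p = 0.0377). Of 7 eosinophil markers Siglecf rose over 5 pairs, and 1 rose and 1 fell over pairs 1 to 3 (camera adjusted p = 0.939 and 0.660). That list had a median of -0.17 and a mean of 0.21 over 5 pairs.

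**Figure D3:**
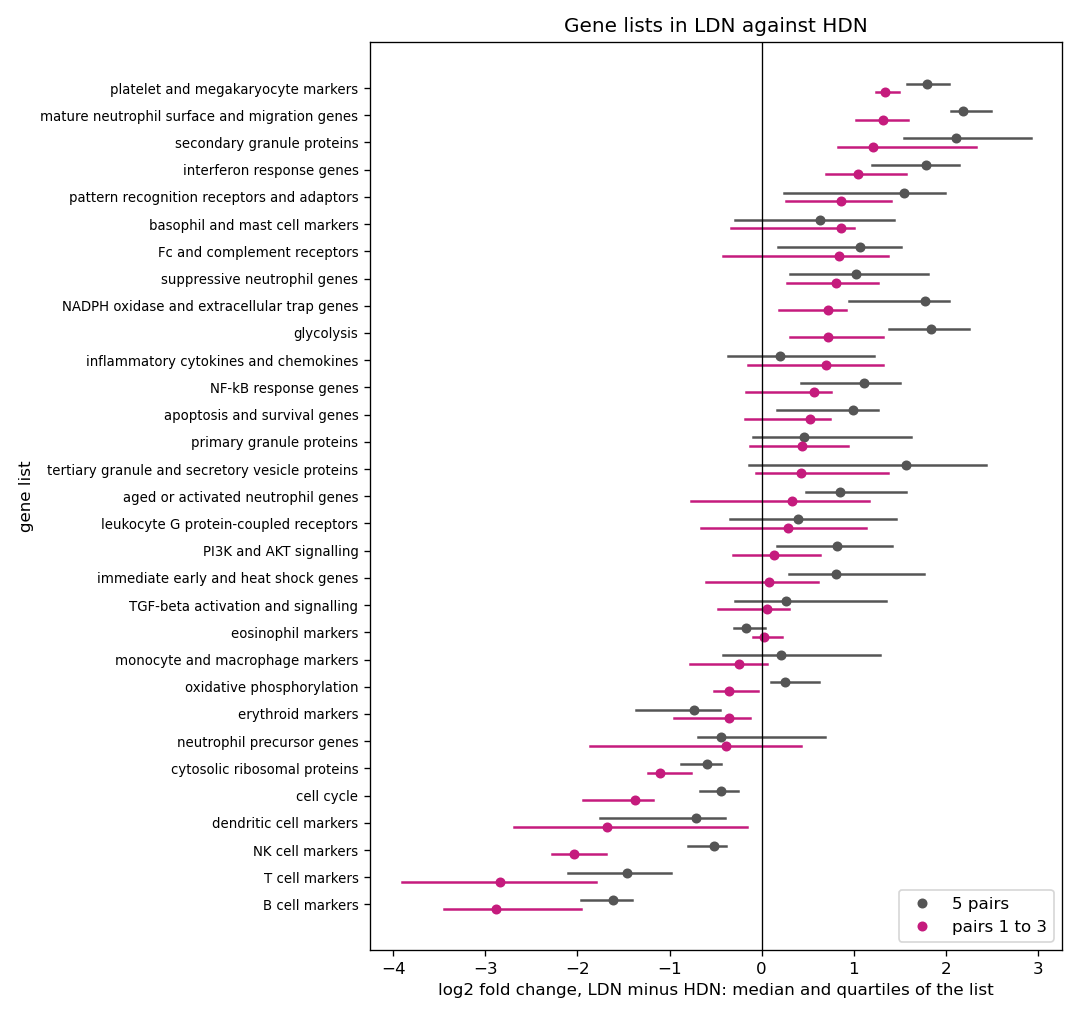
Median log2 fold change of LDN over HDN (horizontal axis) for each of 31 gene lists (vertical axis), over 5 pairs in grey and over pairs 1 to 3 in pink; points are medians over the genes of a list and lines run between the quartiles. The B cell list lay at -1.61 and -2.88 and the platelet list at 1.80 and 1.34 in the 2 comparisons, and the oxidative phosphorylation list had a median of 0.25 over 5 pairs and -0.35 over pairs 1 to 3.

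Over 5 pairs, 25 of the 31 lists passed camera with the preset correlation, 19 higher and 6 lower in LDN. With an estimated correlation no list passed after adjustment and 3 had an unadjusted p under 0.05, while fry, which asks whether a list moves to 1 side on balance, called 6 after adjustment and 13 unadjusted. After cyclic loess 9 of the 25 were lost: primary granule, tertiary granule, aged or activated, cytokine, PI3K, NADPH oxidase, Fc receptor, immediate early and apoptosis. Another 3 passed as lower in LDN: oxidative phosphorylation, monocyte and NK cell. The oxidative phosphorylation and NK cell lists also passed after quantile scaling (adjusted p = 0.0276 and 0.0144). After cyclic loess the median over 5 pairs shrank in several lists that kept their call. It was 0.60 in place of 1.80 for platelet and 0.61 in place of 2.19 for mature neutrophil genes. It was 0.62 in place of 2.11 for secondary granule, 0.47 in place of 1.78 for interferon and 0.49 in place of 1.84 for glycolysis. The B cell and ribosomal protein medians went further down, to -2.02 and -2.47 from -1.61 and -0.59. In pairs 1 to 3, 19 lists passed camera, 11 higher and 8 lower, and none with an estimated correlation (lowest adjusted p = 0.349).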

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

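The tests of red cell RNA, of labelled RNA amount, of degradation, of lymphocyte RNA, of dim against bright genes and of dilution were all chosen only after the results they address were seen, and the comparison over pairs 1 to 3 was as well. The dilution test on secondary granule genes was also rewritten after a first form of it, with a pooled error, had been run and read.

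HDN 4 and HDN 5 stood apart from the other 8 arrays. Of 20 erythroid genes, 13 lay above all 8 on both, against a matched bound of 10 from random lists of like signal, but high erythroid transcripts were what prompted this count, so it leaves red cell RNA in those pools open and does not establish it. A smaller amount of labelled RNA alone would move erythroid genes like others of their level, but their median shift was 1.13, beyond the matched bound of 0.60. The same excess prompted the choice of that list, so the test cannot decide against a smaller amount of RNA. Actin 3' minus 5' signal was 0.97 on HDN 4, below the 1.14 of HDN 2, and 2.44 on HDN 5. Degraded RNA may thus have added to HDN 5, and HDN 4 did not stand out from the other HDN arrays. The signal was 0.91 to 1.14 on HDN 1 to 3 and 0.42 to 0.77 on the LDN arrays, higher in HDN in every pair. For Gapdh it was higher in HDN in all pairs but pair 4 (0.36 on HDN 4, 0.44 on LDN 4). What such a difference of RNA quality between the groups adds to the results was not tested. A real difference between the neutrophils of those mice remains untested.

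Lymphocyte genes were lower in LDN in pairs 1 to 3. Of 49 genes of the B, T and NK lists 46 fell, which is the pattern itself, so the count leaves lymphocyte RNA in the HDN pools open and does not establish it. A shift of dim against bright genes would leave their median near that of lists matched on signal, but it was -2.50, beyond the matched bound of -0.15. The pools had passed a neutrophil purification kit, meant to remove other cells, and neither its yield nor a biological difference was tested.

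Neutrophil genes were higher in LDN in pairs 1 to 3, and dilution of neutrophil RNA by lymphocyte RNA in the HDN pools could raise them all by a shared amount. Of 18 mature neutrophil genes 17 rose, as both dilution and a change of program would give. Of 15 secondary granule genes, 5 (Ltf, Camp, Orm1, Cd177 and Olfm4) passed a test for shifting more than the mature mean of 1.30 ± 0.18 (SE), 3 also passed it against the upper quartile of 1.59, and Cybb and Lyz2 passed for shifting less. A single shared shift accounts for neither those 5 nor Cybb and Lyz2. The shifts of the mature genes spread as well (quartiles 1.03 and 1.59, Itgam 2.29), and the test took no account of that spread. It therefore cannot decide dilution for any of the 15 genes. A change of program in LDN neutrophils was not tested.

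LDN and HDN were swapped within pairs in all 16 ways, where no share under 0.05 can arise. A swap and its mirror image count as 1 and exchange higher and lower, so a count in 1 direction is set against the larger direction of each other swap. As many genes past the limma test arose in 1 of 16 for the total (600, highest other 86), in 1 of 16 for higher genes (525, highest other 86), in 2 of 16 for lower genes (75, highest other 86) and in 1 of 16 for genes changed at least 2-fold (565, highest other 86). As many lists past camera arose in 1 of 16 (25, highest other 23), so swapped labels also gave up to 23 lists past camera at the preset correlation. For pairs 1 to 3, with 4 swaps and no share under 0.25 possible, 1 of 4 gave 5668 genes (highest other 0) and 2 of 4 gave 19 lists. Over the 10 arrays with no replicate block, in 100 drawn splits that ignored the pairs, 1 gave 1206 genes, the real one, and the highest other gave 0.

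Within a group of 5 arrays, 9 of 232 checks found a value far from the other 4, against 11.6 from chance, about 1 in 20 groups. The check looks for 1 value apart from 4, so 2 arrays that deviate together, as HDN 4 and HDN 5 did, can hide each other. The count therefore cannot show that the arrays of a group were alike. Lipg read 10.1 on LDN 5, against 11.2 to 11.6. Tk1 read 6.18 on LDN 5, against 5.19 to 5.46. Ccr1 read 11.96 on LDN 4, against 11.70 to 11.77. Cmpk2 read 10.1 on LDN 2, against 8.63 to 9.04. Ebf1 read 4.61 on HDN 4, against 5.62 to 5.996. The mean of the cytokine and chemokine list was 7.76 on LDN 2, against 6.94 to 7.14. On HDN 5 the 3' minus 5' signal was 2.44 for actin, against 0.91 to 1.14, and 2.35 for Gapdh, against 0.36 to 0.83. On LDN 4 it was 0.44 for Gapdh, against 0.19 to 0.24. Of 9160 probe sets with no gene name, 114 were higher and 35 lower in LDN over 5 pairs, and 464 were higher and 620 lower over pairs 1 to 3.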

How the results depend on the processing

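The comparison without pairs 4 and 5 and the one without HDN arrays 4 and 5 were chosen after the data were seen, and the others were fixed before. Over 5 pairs 525 genes were higher, 75 lower and 565 changed at least 2-fold (limma), and 25 lists passed camera.

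Each pair left out in turn gave 0 to 745 higher genes, 0 to 231 lower and 0 to 874 changed at least 2-fold. The 0 arose in limma without pair 1, 2, 3 or 4, where 2901 to 4006 genes had an unadjusted p under 0.05, and all 59 named genes past the test over 5 pairs lost it there. With no replicate block, ignoring the pairs, 867 genes were higher, 339 lower and 871 changed at least 2-fold. With a random replicate block for the pairs the counts were 1090, 446 and 1046.

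Camera with an estimated correlation called 0 lists (3 with an unadjusted p under 0.05) and fry 6. The mean of all probe sets of a gene gave 988 higher, 207 lower and 879 changed at least 2-fold, and the most variable probe set 36 lower. Centring each array on its median gave 37 lower. Cyclic loess gave 873 higher, 745 lower and 1104 changed at least 2-fold, and quantile normalization 259 higher and 357 changed at least 2-fold. With trend and robust variances 190 were higher, 27 lower and 217 changed at least 2-fold. Array weights gave 3018, 3100 and 2468. Without pairs 4 and 5 the counts were 2756, 2912 and 2409, and without HDN arrays 4 and 5, with no replicate block, 2726, 3215 and 2178.

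Of 59 named genes past the test over 5 pairs, fewer passed under several settings: 31 lost it with trend and robust variances, 30 with quantile normalization, 21 with median centring, 13 with cyclic loess, 9 with the most variable probe set, 6 with the mean of probe sets, 5 with no replicate block, 5 with a random replicate block for the pairs, 4 without pair 5 and 4 without HDN arrays 4 and 5.

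Some genes not past the test over 5 pairs turned sign. The log2 fold change of Cxcr4 (0.76 over 5 pairs) was between -0.0414 (without replicate 5, that is, pair 5) and 1.19 with 1 pair left out, -0.44 with cyclic loess, -0.64 with array weights, -0.59 without pairs 4 and 5 and -0.38 without HDN arrays 4 and 5. The log2 fold change of Elane (0.06) lay between -0.0084 (without replicate 2) and 0.15 with 1 pair left out, and at -0.0076 without replicate 1. The log2 fold change of Itgb8 (0.01) was between -0.0708 (without replicate 1) and 0.0519 with 1 pair left out and -0.0252 with array weights. Arg1 (-0.32) was 0.27 with array weights and 0.14 without pairs 4 and 5. With cyclic loess Sdhd (0.90) was -0.31 and S100a8 (0.28) was -2.00.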

Other observations

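Gene families grouped by symbol stem, a grouping chosen after the data were seen, gave 295 families of at least 8 genes. Of these, over pairs 1 to 3, 33 passed camera at the preset correlation, 6 higher and 27 lower in LDN, 9 of the 33 also passed over 5 pairs in the same direction, and 0 passed camera with an estimated correlation.

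The Gimap family of lymphocyte GTPases had a median log2 fold change of -2.75 over pairs 1 to 3, with 8 of 8 genes lower in LDN. Other families lower there, picked after their values were seen, were Rpl (-1.05, 19 of 24 lower), Rps (-0.82, 19 of 30, 1 higher), Eif (-0.47, 24 of 47, 5 higher), Nop (-1.26, 8 of 8), Cct (-1.38, 7 of 9), Mrps (-0.70, 20 of 29) and Mrpl (-0.63, 27 of 47, 4 higher). The replication family Mcm had a median of -1.44, with 8 of 10 lower. The Rab family of vesicle traffic (0.37, 34 of 72 higher, 4 lower) and the Tlr family (0.69, 7 of 11 higher) were on the other side. Of the families named, Rpl, Rps, Rab and Tlr also passed over 5 pairs (camera adjusted p = 0.00544, 0.0259, 0.00011 and 0.0122). The others did not pass: Gimap (median -1.13, adjusted p = 0.136), Nop (-0.65, 0.167), Mrps (-0.27, 0.224), Mrpl (-0.27, 0.550), Mcm (-0.52, 0.611), Cct (-0.15, 0.722) and Eif, whose median had the other sign (0.40, 0.163; -0.43 after cyclic loess and 0.04 after quantile scaling). All of these kept their direction over pairs 1 to 3 under median centring, cyclic loess and quantile scaling. The B and T cell marker lists were lower in the same LDN pools, and a family median in a mixed pool does not say which cells carry the change.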
